A study of Homo sapiens with 6 samples.

How the data were processed

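Single-cell RNA sequencing was done on fragments of retinal organoids made from WA09, an established human embryonic stem cell line, here with a tdTomato reporter placed under control of CRX, a transcription factor of photoreceptor precursors. Per the labels, the organoids were between day 113 and day 126 of differentiation, and the transplanted samples were taken 3 days after subretinal injection into normal dog eyes. The cultured samples were fragments of the same batches kept in a dish for 3 days. The labels state 3 independent experiments, called Sets, each with 1 cultured and 1 transplanted sample, so n = 3 per group and the Set number pairs the samples. The deposited matrices hold raw UMI counts (unique molecular identifiers, an integer count per gene and cell barcode) with no normalization. Per the file headers, Set 1 was processed by the authors with Cell Ranger 6.0.2 and Sets 2 and 3 with Cell Ranger 7.1.0, on the human genome GRCh38. Whether intronic reads were counted is not stated, and both samples of a Set went through the same version. Each matrix held 36601 genes, and none of them was tdTomato. Gene positions came from GENCODE v29, whose identifiers matched 34515 of the 36601 genes.

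Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were scored per sample with Scrublet in Scanpy 1.11.5 (30 components). Its automatic threshold called almost no cells, so the cells with the highest scores were removed up to an expected rate of 0.8% per 1000 cells. Counts were log-normalised, 2000 variable genes were chosen, and 30 principal components were computed. The first clusters split by Set, so genes were scaled within each Set and the components were adjusted for Set with Harmony (50 clusters, theta 2). A graph of 15 neighbours was clustered with Leiden at resolution 1 (igraph 0.11.9). Clusters were named from fixed lists of cell type markers. A name needed 20 cells in a Set, a marker score of 0.5 with a lead of 0.2 over the next list, and at least 3 markers detected at 10 counts-per-million (CPM). It also needed a marker of its own list among the 10 leading genes of the cluster, with no other list having more there. Markers among the 50 leading genes were counted too, but did not decide a name. These naming rules were tightened after the clusters had been seen, and clusters that missed them stayed unnamed. Dog reads can align to human genes, so the share of transcripts named only by a clone, which few dog reads should match, was compared with that of cultured cells of the same Set. A cluster under a ratio of 0.5 was left unnamed, and a host filter that drops cells below the 1st percentile of cultured cells served as an alternative.

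Raw counts were summed per sample over the cells of each class with at least 20 cells in the sample. The test chosen before the data were examined was the edgeR 4.0.16 quasi-likelihood test without a term for the Set (filterByExpr, TMM factors, robust fit, R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method over all genes kept, at a threshold of 0.05. The lists, the markers and most of the alternatives were also chosen before the data were examined. The same test with the Set as a block was one of those alternatives. On simulated data with the depths and Set differences of these samples (dispersion 0.05, 200 changed genes), the unblocked test recovered 0% of 4-fold changes in each of the 5 classes simulated. There the block test recovered 94.9% of 4-fold changes in rods, 93.75% in cones, 73.4% in Müller glia, 85.06% in amacrine cells and 56.99% in horizontal cells. For 2-fold changes it recovered 22.92%, 30.85%, 7.143%, 10.99% and 3.297%, and at most 5 unchanged genes were called in any of these classes. The simulation gave both samples of a Set the same mean profile apart from the changed genes, with a fixed dispersion. It held no variation of the response between Sets, which favours the block test. These figures are therefore not its recovery or false calls in the real data. The log2 changes and gene calls below are those of the block test, a choice made after the unblocked counts had been seen, and the unblocked counts stand beside them. Positive log2 changes are higher in transplanted samples, and ± beside a log2 change is its SE.

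Named genes followed a rule fixed in advance and applied to the block test after the unblocked test had called none. They are the 12 genes with the largest rise and the 12 with the largest fall in rods, 8 and 8 in cones and in Müller glia, and 3 and 3 in the other classes. Each had to pass the adjusted threshold, reach a mean of 30 CPM in the higher group and have the same sign in every Set pair. Clone-named, mitochondrially encoded, ribosomal and sex-chromosome marker transcripts were left out of this rule. CRX, and 2 to 4 members of each gene list, were also taken. The difference between the responses of rods and cones, or of rods and Müller glia, was tested as a class by treatment interaction with 1 term per sample, and 5 and 5 genes were named from it. For 28 fixed gene lists, limma 3.58.1 camera was run with a preset correlation of 0.01, with an estimated correlation, and beside fry, and adjusted over the lists of a class. The camera and fry results below, also those with a sample left out, come from the fit without the Set unless the block is named. The counts of genes called beside them are those of the block test. With the block and the preset correlation, camera called 12, 13 and 13 lists in rods, cones and Müller glia. Shares of cells were compared with a 2-sided exact permutation test in SciPy 1.17.1, and intervals are exact Clopper-Pearson at 95%. They cover counting error only.

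The alternatives tried were DESeq2 1.42.0, relative log expression factors, no expression filter, a stricter cell filter (2000 UMIs, 10% mitochondrial), doublets kept, equal cells per sample, the host filter, Leiden at resolutions 0.5 and 2, and leaving out each sample. Combinations of the block with each of these, leaving out each Set, leaving out rod cluster 11 or 4, and interaction models with class by Set terms were added after seeing the data. Of the rod clusters, the 1st choice was the one with the largest difference in share (cluster 4), and cluster 11 was added after it. The checks on cholesterol genes used every member kept with all cells, with cone sums thinned to the smallest total for equal UMIs and cones drawn in equal numbers per bin of mitochondrial share within Sets. A bound of 0.5 of the full median, with a rule on the upper quartile or on 2 SE, was tried first, and the rule kept asked for a median below 0 by 2 SE, in each Set, and an upper quartile below 0. Retinal pigment epithelium (RPE) had no residual degrees of freedom in the block test, so it has no block value. Cells of unnamed clusters entered the shares but no gene test.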

Results

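Gene expression was measured per cell in 6 samples of human retinal organoid fragments, 3 cultured and 3 transplanted, paired within Sets 1, 2 and 3. Cultured samples 1, 2 and 3 held 74298633, 108222149 and 8000032 UMIs, and transplanted samples 1, 2 and 3 held 45281930, 6850189 and 43989876 UMIs. After filtering, 15045, 9646 and 1850 cultured cells and 7246, 686 and 4535 transplanted cells remained. Their median depth was 2733, 4082 and 2109.5 UMIs in the cultured samples and 3166, 3367.5 and 3388 UMIs in the transplanted samples. Values below are means ± SD over n = 3 samples per group unless another n is given. As the labels describe it, the comparison asks how the grafted cells differ from their cultured siblings at 3 days, and whether each retinal cell class responds alike.

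Rods made up a larger and cones a smaller share of the transplanted cells in each Set, by differences that 3 against 3 samples cannot separate from chance at the 0.05 threshold. Rods were 13.8% ± 3.67 of kept cells in cultured samples and 21.6% ± 2.29 in transplanted samples. Cones were 15.2% ± 2.04 in cultured and 8.94% ± 2.92 in transplanted samples. Amacrine cells (10.8% ± 5.77 against 3.83% ± 1.28), bipolar cells (3.21% ± 2.51 against 0.784% ± 0.660) and horizontal cells (4.91% ± 3.33 against 1.59% ± 1.02) were lower in the transplanted sample of 3 of 3 Sets. Dividing progenitors (5.16% ± 5.44 against 1.19% ± 1.37), neurogenic precursors (1.52% ± 1.02 against 0.300% ± 0.379), astrocytes (1.82% ± 2.12 against 0.690% ± 0.805) and mural cells or fibroblasts (1.45% ± 1.60 against 0.650% ± 0.743) were lower in 3 of 3 Sets as well. Müller glia held 18.7% of transplanted sample 1 (interval 17.8 to 19.6%), 1.60% of transplanted sample 2 (0.803 to 2.85%) and 2.43% of transplanted sample 3 (1.998 to 2.92%), against 5.89% ± 1.38 in cultured samples. The exact permutation p was 0.10 for rods and for cones, the smallest this design allows, and 0.40 for both when adjusted over 12 classes. The exact permutation p of the remaining classes lay between 0.20 and 1. At Leiden resolution 0.5 the cone difference shrank from -6.27 to -1.63 percentage points (exact permutation p = 0.70) and the rod difference from 7.79 to 4.93. The latter was 26.1 over named classes only and 13.8 with the stricter cell filter. Dividing progenitors moved from -3.97 to -0.858 without cultured 1, and neurogenic precursors from -1.22 to -0.681, bipolar cells from -2.42 to -1.13 and horizontal cells from -3.32 to -1.75 without cultured 3. Without cultured 1 the differences of astrocytes and of mural cells or fibroblasts changed sign. Unnamed clusters held 35.4% ± 6.20 of cultured and 52.2% ± 12.1 of transplanted cells (a difference of 16.8 points, and 7.53 with the stricter cell filter), among them a cluster led by PDE6H in which the cone and rod lists scored alike.

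**Figure D1:**
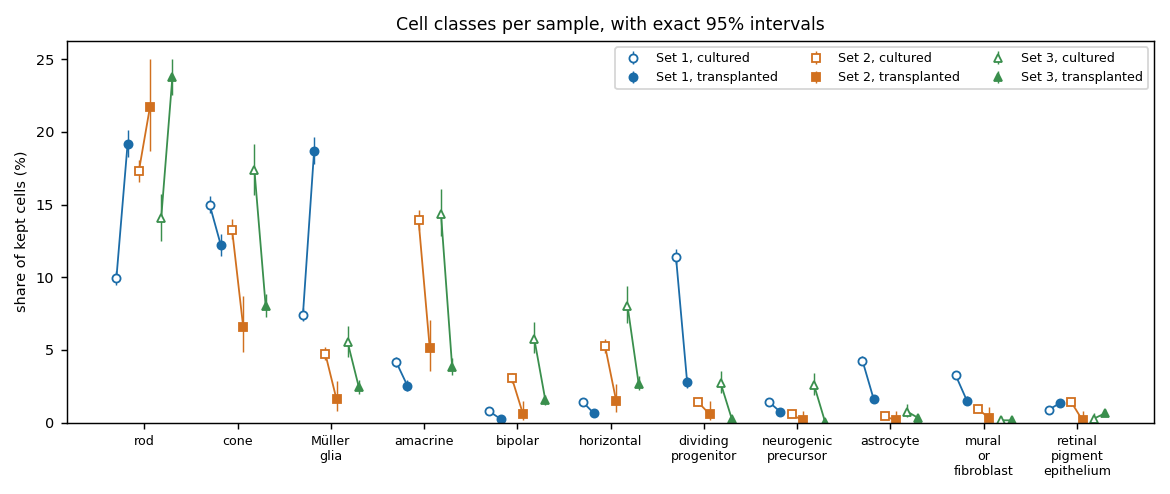
Share of kept cells (%) in each class, with 1 point per sample and exact 95% intervals that cover counting error. Rods lie higher and cones lower in the transplanted sample of each of the 3 Sets, while Müller glia reach 18.7% in transplanted sample 1.

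Transplanted rods had less GNGT1 and GNGT2 RNA and more GUCA1B, CEBPD and SOCS3 RNA. GNGT2 (ENSG00000167083), the gamma subunit of cone transducin, fell from 558 ± 139 to 132 ± 15.1 CPM, a log2 change of -2.05 ± 0.27 (adjusted p = 0.00169). It lies on chromosome 17 of GRCh38 from 49202791 to 49210574. GNGT1 (ENSG00000127928), the gamma subunit of rod transducin, fell from 104 ± 17.5 to 23.5 ± 15.9 CPM (-2.42 ± 0.34, adjusted p = 0.00326). GUCA1B (ENSG00000112599), which activates retinal guanylate cyclase, rose from 29.96 ± 16.2 to 116 ± 33.6 CPM (1.95 ± 0.25, adjusted p = 0.00143). CEBPD (ENSG00000221869), a transcription factor of the acute-phase response, rose from 51.8 ± 55.3 to 160 ± 72.2 CPM (1.99 ± 0.31, adjusted p = 0.00748), and SOCS3, an inhibitor of cytokine signalling, rose by 1.59 ± 0.33 (adjusted p = 0.0306). SAMD7, a repressor that keeps rods from expressing genes of other photoreceptors, fell by 2.67 on the log2 scale, from 44.2 ± 33.5 to 6.73 ± 5.89 CPM (adjusted p = 0.000989).

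With the Set as a block, 196 of 15584 genes were called in rods, 108 higher and 88 lower in transplanted samples, with 2157 genes at an unadjusted p under 0.05. Without the block, edgeR called 0 genes, with 193 at an unadjusted p under 0.05, and DESeq2 called 1. The other named genes that rose were CCDC172, PPP1R27, MMP2-AS1, TMEM176B, TMEM176A, H19, HSPA1A, TRHDE and MTRNR2L12, by 1.61 to 3.99 on the log2 scale. Those that fell were TOP2A, STAT4, GPR160, CCKBR, MIR181A1HG, DPYD, ZBTB7C, PTN and KCNG4, with log2 changes from -3.32 to -1.49. TMEM176B, a membrane protein that also led the genes of rod cluster 11, rose from 173 ± 153 to 547 ± 186 CPM (2.17 ± 0.46, adjusted p = 0.0341). That cluster held 7.45% of rods in cultured and 22.7% in transplanted samples, and without it the change in TMEM176B was 2.15 (adjusted p = 0.00509), whereas the call ended with DESeq2 (2.31, adjusted p = 0.343) and the stricter cell filter (2.18, 0.0921). DESeq2 also ended the calls of TRHDE and KCNG4, and equal cells those of H19 and TRHDE, with 17 of the 24 named genes measured. Without rod cluster 4, 13 of 22 measured named genes were called (SOCS3 adjusted p = 0.0675, HSPA1A 0.129, CCKBR 0.156, KCNG4 0.423). HSPA1A has a near-identical copy, MTRNR2L12 resembles mitochondrial ribosomal RNA and MMP2-AS1 is an antisense transcript, so reads of other genes may be counted in them. CRX was 350 ± 146 CPM in cultured and 265 ± 54.0 CPM in transplanted rods, with no change called (-0.34 ± 0.26, adjusted p = 0.605). The count was 55 without Set 1, 448 without Set 3, 72 with equal cells per sample, 114 with DESeq2 and 32 without rod cluster 4, the main rod cluster (86.6% of cultured and 67.9% of transplanted rods). All 24 named genes kept their sign without each Set, which followed from the naming rule, as it asked for the same sign in every Set pair. Calls ended for HSPA1A, TRHDE, MTRNR2L12, MIR181A1HG, ZBTB7C and PTN without Set 1 (adjusted p from 0.0555 to 0.180), for SOCS3 (0.0798), KCNG4 (0.0539), TRHDE (0.0938) and MTRNR2L12 (0.0992) without Set 2, and for SOCS3 (0.206), GNGT1 (0.0722), CCKBR (0.169) and KCNG4 (0.0510) without Set 3.

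**Figure D2:**
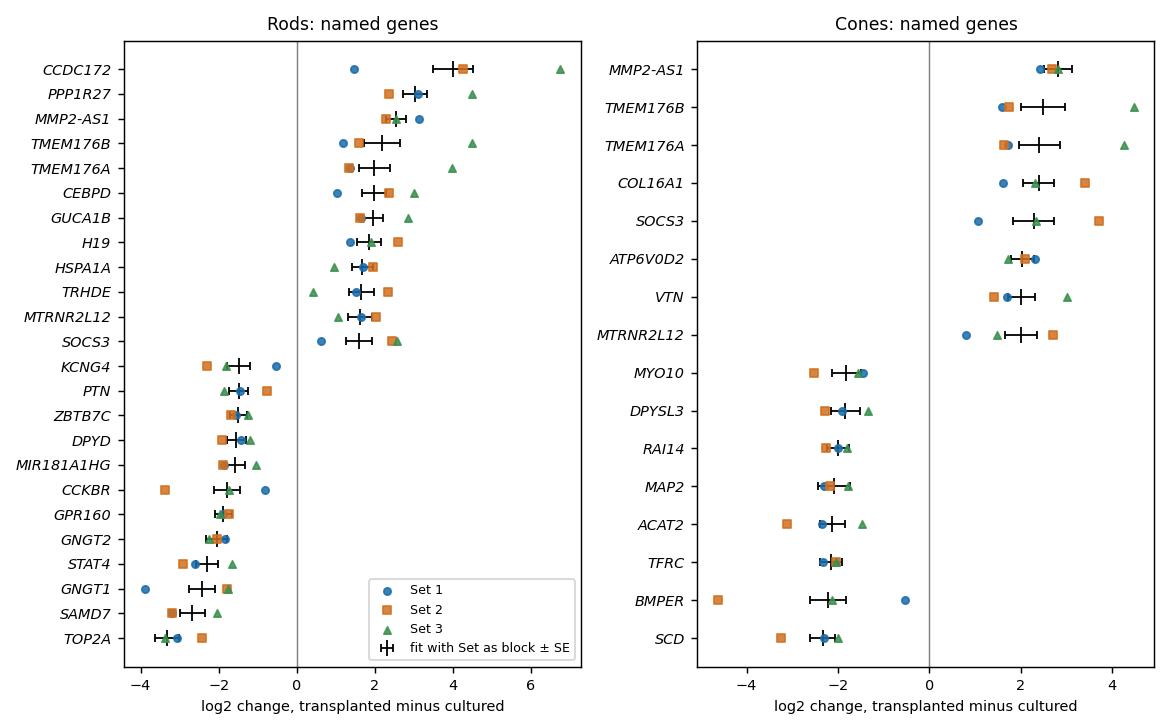
Log2 change of each named gene in rods and cones, transplanted against cultured, with the Set as a block and error bars of 1 SE, and 1 point per Set. In rods the block changes run from -3.32 for TOP2A to 3.99 for CCDC172, and in cones from -2.33 for SCD to 2.81 for MMP2-AS1.

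Among the fixed lists, immediate early genes were higher and cell cycle genes lower in transplanted rods. Of 22 immediate early genes, 3 rose (13 when adjusted over the list alone), among them JUN, from 278 ± 104 to 733 ± 315 CPM (1.39), and BTG2, from 140 ± 141 to 299 ± 196 CPM (1.36). The camera adjusted p was 4.93e-09 for this list, and the adjusted p = 0.623 with an estimated correlation. Of 12 genes of MHC class I antigen presentation, 2 rose (4 when adjusted over the list alone): HLA-B from 24.6 ± 20.5 to 69.5 ± 43.7 CPM (1.57 ± 0.23, adjusted p = 0.00428) and HLA-C from 71.2 ± 54.5 to 156 ± 86.3 CPM (1.32 ± 0.28, adjusted p = 0.0351). The list had a camera adjusted p of 0.00417, or adjusted p = 0.623 with an estimated correlation, and HLA genes share sequence with one another. Summed T or NK cell markers in rods rose too, from 5.52 ± 5.10 to 21.1 ± 7.88 CPM in 3 of 3 Sets, with all but TRAC at 0.285 CPM or less in any sample. Of 15 cell cycle genes, 5 fell (7 when adjusted over the list alone), including TOP2A, BIRC5, CENPF and MKI67 (camera adjusted p = 2.03e-05, adjusted p = 0.623 with an estimated correlation). Summed markers of dividing progenitors within rods were 119 ± 87.3 CPM in cultured and 36.6 ± 11.9 CPM in transplanted samples, lower in 3 of 3 Sets. All 8 of these markers belong to the cell cycle list, so their sum is not a separate observation. Dividing progenitors also held a smaller share of the transplanted sample in 3 of 3 Sets. Their RNA in the droplets of rods was not tested as a source of the fall. In rod phototransduction, GUCA1B rose and GNGT1 and PDE6G (-1.23) fell among 16 genes (1 up and 4 down when adjusted over the list alone). That list was not called (camera adjusted p = 0.304). PCARE, a gene of outer segment formation, rose from 49.0 ± 8.49 to 116 ± 13.1 CPM (1.24), NQO1 fell by 1.75 and the immaturity gene DPYSL3 by 1.24 on the log2 scale. Up to 4 called members per list, those with the smallest p, were followed without each Set. Of the 23, 24 and 24 measured in rods, 9 remained called without Set 1, 17 without Set 2 and 22 without Set 3. Each kept its sign, as was likely for members picked by their call over all Sets. HLA-B, TOP2A, GUCA1B and DPYSL3 remained called in each case, and BIRC5, not measured without Set 1, in the other cases. Among the calls that ended were those of HLA-C (adjusted p = 0.111), CENPF (0.671), MKI67 (0.742), PCARE (0.0558) and NQO1 (0.0572) without Set 1, JUN (0.225 and 0.0539) and PDE6G (0.485 and 0.0798) without Set 1 or 2, BTG2 (0.0938) without Set 2, and GNGT1 (0.0722) without Set 3.

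Mitochondrially encoded transcripts (camera adjusted p = 2.58e-08) and ribosomal protein transcripts (3.06e-10) were higher as lists in transplanted rods, with 0 of 13 and 0 of 82 genes called by edgeR with the Set as a block, over all genes and adjusted over the list alone. With an estimated correlation the adjusted p = 0.623 for each. The median mitochondrial share per rod was 1.78%, 3.20% and 1.16% in the cultured samples and 4.35%, 3.72% and 3.22% in the transplanted samples. Nuclear genes of oxidative phosphorylation were lower as a list, with a median of -0.37 with the block and medians of -0.56, -0.43 and 0.02 in Sets 1, 2 and 3. Camera gave adjusted p = 0.00186 without the block (0.733 with an estimated correlation) and 1.99e-05 with it (0.638 with an estimated correlation). Of the 28 lists, 14 were called in rods with the preset correlation, and 0 with an estimated correlation or with fry (lowest adjusted p = 0.533). Only the immediate early and mitochondrially encoded lists were called whichever sample was left out. MHC class I, for example, had adjusted p = 0.569 without cultured 3 and 0.305 without transplanted 1, cell cycle 0.476 without cultured 1, and ribosomal proteins 0.259 without cultured 3 and 0.325 without transplanted 1. Oxidative phosphorylation turned higher without cultured 1 (adjusted p = 0.0217) and lost its call without transplanted 2 (0.429) or transplanted 3 (0.537).

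Transplanted cones had less TFRC, SCD, ACAT2, MAP2 and DPYSL3 RNA. TFRC (ENSG00000072274), the transferrin receptor that imports iron, fell from 127 ± 29.8 to 28.7 ± 6.60 CPM (-2.16 ± 0.25, adjusted p = 0.000221). It lies on chromosome 3 of GRCh38 from 196027183 to 196082189. SCD (ENSG00000099194), which desaturates fatty acids, fell from 39.8 ± 14.0 to 6.91 ± 3.54 CPM (-2.33 ± 0.28, adjusted p = 0.000231; -0.93 with equal cells per sample, adjusted p = 0.440), and ACAT2 (ENSG00000120437), an early enzyme of cholesterol synthesis, from 72.1 ± 32.8 to 14.4 ± 6.68 CPM (-2.12 ± 0.28, adjusted p = 0.000614). MAP2, a microtubule protein of dendrites, fell from 676 ± 201 to 166 ± 76.6 CPM (-2.08 ± 0.34, adjusted p = 0.00406). DPYSL3, which acts in axon growth, fell from 447 ± 61.4 to 125 ± 23.9 CPM (-1.84 ± 0.33, adjusted p = 0.00534). VTN, the secreted protein vitronectin, rose from 32.3 ± 17.6 to 123 ± 36.3 CPM (2.02 ± 0.29, adjusted p = 0.00175).

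With the Set as a block, 369 of 15215 genes were called in cones, 189 higher and 180 lower in transplanted samples, with 2434 at an unadjusted p under 0.05. Without the block, edgeR called 0 genes, with 333 at an unadjusted p under 0.05, and DESeq2 called 5. The other named genes that rose were MMP2-AS1, TMEM176B, TMEM176A, COL16A1, SOCS3, ATP6V0D2 and MTRNR2L12, by 2.01 to 2.81 on the log2 scale, and BMPER (-2.21), RAI14 (-1.99) and MYO10 (-1.81) fell. GNGT2 fell in cones too, from 511 ± 129 to 154 ± 26.9 CPM (-1.72 ± 0.32, adjusted p = 0.00714; 0.168 without Set 1). Between rods and cones, 66 genes were called higher in both and 44 lower in both, against 1.35 and 0.996 if the calls were independent. Both classes come from the same libraries. CRX was 328 ± 111 CPM in cultured and 313 ± 55.4 CPM in transplanted cones, with no change called (-0.03 ± 0.31, adjusted p = 0.974). The median mitochondrial share per cone was 1.35%, 1.34% and 0.596% in cultured and 3.89%, 2.01% and 3.16% in transplanted samples. Mitochondrially encoded transcripts were higher as a list in cones (camera adjusted p = 1.89e-11, adjusted p = 0.373 with an estimated correlation), with 0 of 13 called over all genes and 9 when adjusted over the list alone. A cluster with a low mitochondrial share held 60.7% of the cones of cultured sample 3, while another cluster held most cones of every other sample. The count was 12 without Set 1 and 557 without Set 3, 74 with equal cells per sample, 189 with the stricter cell filter, 135 at Leiden resolution 0.5 and 165 with DESeq2. Of the 16 named genes, MMP2-AS1, COL16A1, SOCS3 and TFRC remained called without Set 1 (SCD adjusted p = 0.0803, ACAT2 0.120, MAP2 0.147), and SOCS3 was not called without Set 3 (adjusted p = 0.478) or at Leiden resolution 0.5 (0.0839). Each kept its sign, which for the Sets left out followed from the naming rule.

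Of 21 cholesterol synthesis genes, 8 were called lower in transplanted cones and 0 higher (14 lower when adjusted over the list alone). HMGCS1 (ENSG00000112972), which makes the precursor of mevalonate, fell from 88.5 ± 6.25 to 26.8 ± 4.67 CPM (-1.78 ± 0.24, adjusted p = 0.000666), and FDFT1, squalene synthase, from 53.9 ± 18.7 to 20.8 ± 4.82 CPM (-1.32). The median change of the list was -0.92 with the block and -1.01, -1.04 and -0.91 within Sets 1, 2 and 3. For it, camera gave adjusted p = 1.37e-12 without the block (0.373 with an estimated correlation) and 9.52e-09 with it (0.515 with an estimated correlation). In rods 1 of 20 of these genes was called lower, HMGCS1 by 0.90 on the log2 scale (adjusted p = 0.0498, and 1 gene when adjusted over the list alone). The rod list was lower too, with a block median of -0.37 and medians of -0.30, -0.30 and -0.17 in Sets 1, 2 and 3. Its camera adjusted p was 0.00285 (0.623 with an estimated correlation), and the call ended without cultured 1 (0.751) or transplanted 3 (0.164). In Müller glia edgeR called 0 of 21 with the Set as a block, and 0 when adjusted over the list alone. Immediate early genes rose in cones, 10 of 19 by the gene test (16 when adjusted over the list alone), with JUN from 179 ± 50.6 to 546 ± 163 CPM (1.61), JUNB by 1.51 and DUSP1 by 1.08 (camera adjusted p = 9.32e-12, adjusted p = 0.478 with an estimated correlation). Of 8 MHC class I genes, 3 rose (4 when adjusted over the list alone), among them HLA-B by 1.86 and HLA-C by 1.84 (camera adjusted p = 0.00442, adjusted p = 0.520 with an estimated correlation). Of 19 genes of endoplasmic reticulum stress, DNAJB9 (1.28), SDF2L1 (1.05) and HERPUD1 (1.03) rose (7 when adjusted over the list alone; camera adjusted p = 0.000220, adjusted p = 0.570 with an estimated correlation). Neuronal immaturity genes were lower as a list (camera adjusted p = 0.00395, adjusted p = 0.663 with an estimated correlation), with DPYSL3 and GAP43 (-1.30) fallen among 17 genes (2 when adjusted over the list alone). Summed retinal ganglion markers, GAP43 among them, were 53.2 ± 6.99 CPM in cultured and 27.3 ± 10.55 CPM in transplanted cones, and horizontal markers 414 ± 51.7 and 318 ± 66.6 CPM, lower in 3 of 3 Sets. Of 20 outer segment genes, PRPH2 (1.01) and PCARE (1.31) rose in cones (3 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0769). Of the 28 lists, 14 were called in cones with the preset correlation, and 0 with an estimated correlation or with fry (lowest adjusted p = 0.210). Of 40 called members followed in cones, up to 4 per list with the smallest p, 3 remained called without Set 1 (adjusted p from 0.0803 to 0.754 for the others, HMGCS1 at 0.120), 32 without Set 2 (JUN at 0.0668, JUNB at 0.0995) and 34 without Set 3 (JUNB at 0.230). Each kept its sign, as was likely for members picked by their call over all Sets. The MHC class I call ended without cultured 3 (adjusted p = 0.124), the endoplasmic reticulum call without cultured 3 (0.122) or transplanted 1 (0.240), and the immaturity call without cultured 1 (0.903), transplanted 2 (0.133) or transplanted 3 (0.139).

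Transplanted Müller glia had far more SERPINA3 RNA, more C1QTNF3 and HSPA1A RNA, and less TOP2A RNA. SERPINA3 (ENSG00000196136), an acute-phase protease inhibitor and marker of reactive glia, rose from 3.92 ± 1.87 CPM (n = 3) to 120 ± 57.4 CPM (n = 2), a log2 change of 5.20 ± 0.50 (adjusted p = 4.34e-21). It lies on chromosome 14 of GRCh38 from 94612377 to 94624055, and in rods it stood at 0.181 ± 0.161 CPM in cultured and 5.98 ± 5.31 CPM in transplanted samples. C1QTNF3, a secreted protein related to complement C1q, rose by 3.17 ± 0.44 (adjusted p = 4.92e-09), and HSPA1A, an inducible heat shock protein, by 2.45 ± 0.42 (adjusted p = 1.12e-05). TOP2A, which untangles DNA in dividing cells, fell from 66.3 ± 67.4 to 17.3 ± 15.9 CPM (-2.20 ± 0.41, adjusted p = 0.000111), a call that ended with DESeq2 (-2.11, adjusted p = 0.1885) and equal cells per sample (-1.81, 0.0547). GNGT2, a photoreceptor gene, fell in these glia too, from 91.7 ± 74.9 to 19.0 ± 16.6 CPM (-2.55 ± 0.37, adjusted p = 4.95e-08). With 2 pairs in this class, the small adjusted p-values lean on variance shared across genes more than on the spread of replicates. They do not mean stronger evidence than those of rods or cones.

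With the Set as a block, 159 of 14862 genes were called in Müller glia, 55 higher and 104 lower, with 1361 at an unadjusted p under 0.05. Transplanted sample 2 had 11 Müller cells and was left out, so the block rested on 2 pairs. Without the block, edgeR called 0 genes, with 119 at an unadjusted p under 0.05, and DESeq2 called 2. The other named genes that rose were NPVF, H19, LST1, PHLDA2 and PAPPA2, by 2.24 to 3.39 on the log2 scale. GPR160, NUSAP1, SVEP1, CENPF, CABP5 and CHST9 fell, with log2 changes from -2.36 to -1.96. Of 16 cell cycle genes, 6 fell (9 when adjusted over the list alone), including BIRC5 and MKI67 (camera adjusted p = 0.000226, adjusted p = 0.627 with an estimated correlation). Summed markers of dividing progenitors, all of them members of that list, fell in these glia from 262 ± 232 to 79.5 ± 74.4 CPM, in 2 of 2 Sets. RNA of dividing progenitors, whose share was lower in each Set, was not tested as a source in the droplets of these glia. Of 14 interferon response genes, IFITM1 (36.1 ± 44.1 to 158 ± 175 CPM, 2.10) and BST2 (1.59 ± 1.46 to 12.6 ± 13.6 CPM, 3.56) rose (4 when adjusted over the list alone; camera adjusted p = 0.000226, adjusted p = 0.540 with an estimated correlation). Of 9 inflammatory genes, NFKBIA (1.36) and ICAM1 (1.67 ± 2.21 to 11.7 ± 2.54 CPM, 3.77) rose (4 when adjusted over the list alone; camera adjusted p = 2.42e-05, adjusted p = 0.540 with an estimated correlation). Of 13 heat shock genes, HSPA1A and HSPA1B (1.62) rose (3 when adjusted over the list alone; camera adjusted p = 2.42e-05, adjusted p = 0.540 with an estimated correlation). Rod phototransduction genes were lower as a list (camera adjusted p = 0.000931, adjusted p = 0.627 with an estimated correlation), with 1 of 14 genes called (2 when adjusted over the list alone). Summed rod markers in these glia were 600 ± 252 CPM in cultured and 385 ± 321 CPM in transplanted samples. Mitochondrially encoded (camera adjusted p = 1.44e-05) and ribosomal protein transcripts (1.83e-19) were higher as lists, each with 0.540 under an estimated correlation and 0 genes called. The median mitochondrial share per Müller cell was 1.96%, 4.97% and 1.03% in cultured samples 1, 2 and 3. In transplanted samples 1 and 3 it was 4.97% and 3.34%. Of the 28 lists, 16 were called in Müller glia with the preset correlation, and 0 with an estimated correlation or with fry (lowest adjusted p = 0.438). The heat shock call ended without transplanted 1 (adjusted p = 0.0784). The interferon call ended there too (adjusted p = 0.963), where IFITM1 was lower (-0.13), the cell cycle list turned higher without transplanted 3 (0.531) and lost its call without cultured 1 (0.547), and rod phototransduction turned higher without transplanted 1 (0.902). NFKBIA was not called without Set 2 (0.0612), which held no pair in this class, so the same 2 pairs remained. With the block, DESeq2 called 9 genes, 4 of them among the 159, and 3 of the 8 named genes for which it gave a value (NUSAP1 adjusted p = 0.175, CENPF 0.363, CABP5 0.0927, NPVF 0.801). Of the 16 named genes, 9 were called at Leiden resolution 2 and 15 with the host filter (NPVF 0.843), and the count was 406 and 51 at Leiden resolutions 0.5 and 2, 47 with equal cells per sample and 101 with no expression filter.

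**Figure D3:**
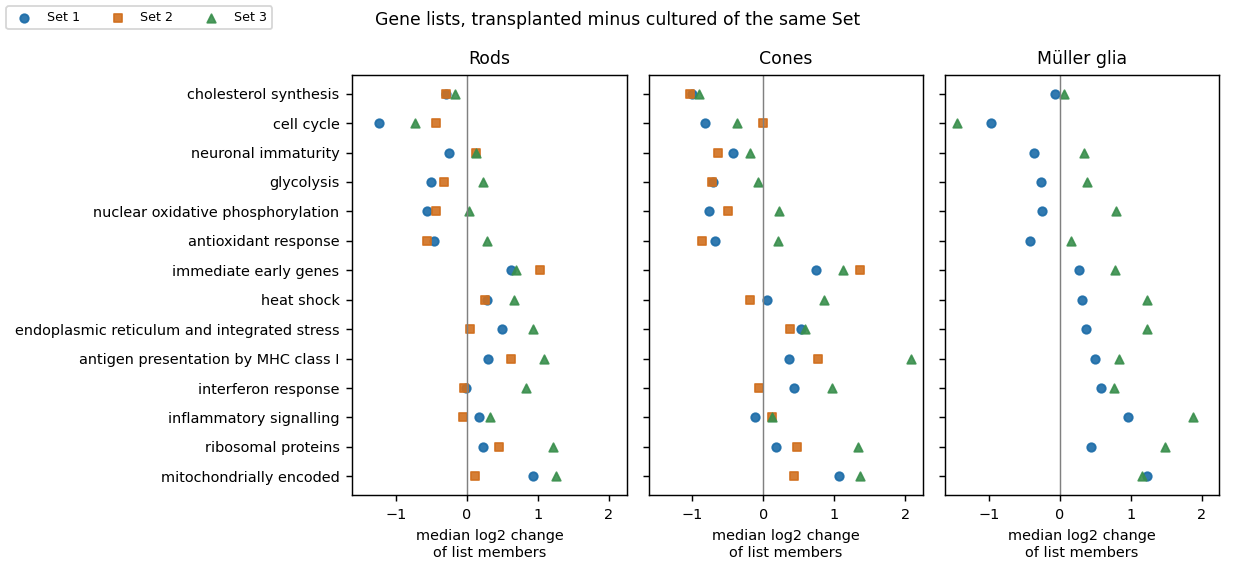
Median log2 change of 14 of the 28 gene lists within each Set, transplanted minus cultured, for rods, cones and Müller glia, with 1 point per Set and 2 Sets for Müller glia. Cholesterol synthesis lies at -1.01, -1.04 and -0.91 in cones, and immediate early genes lie above 0 in every class and Set.

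Amacrine and horizontal cells gave fewer calls. HMGCS1 fell in transplanted amacrine cells, from 105 ± 9.55 to 22.4 ± 5.27 CPM (-2.17 ± 0.33, adjusted p = 0.00105), as did TNC (-2.26) and CCND1 (-1.98), while AIPL1 (1.90), TMEM176B (1.86) and GPC5 (1.65) rose. AIPL1 was among the leading genes of rod and cone clusters, TMEM176B of a rod cluster and GPC5 of an unnamed cluster. RNA of other cells in the droplets of amacrine cells was not tested as a source of these rises. CALB1, a calcium-binding protein of horizontal cells, fell in those cells from 59.6 ± 42.5 (n = 3) to 2.67 ± 3.77 CPM (n = 2), a log2 change of -3.20 ± 0.72 (adjusted p = 0.00882). CDH13 (-3.56) and HES1 (-3.23) fell there as well, and CFAP20 (2.51), CCDC82 (1.77) and EIF5 (1.74) rose. The block test called 18 of 10033 genes in amacrine cells, 7 higher and 11 lower, and 19 of 8005 in horizontal cells, 3 higher and 16 lower. Without the block, edgeR called 0 genes in amacrine cells, horizontal cells and RPE, with 50, 12 and 53 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each. The amacrine count was 0 without Set 1 and 39 without Set 2, HMGCS1 had adjusted p = 0.505 without Set 1, and TMEM176B had 0.0771 without Set 2 and was lower without transplanted 1 in the unblocked test (-0.12). AIPL1 was not called without Set 1 (0.505), TNC and CCND1 without Set 1 (0.916 each) or Set 3 (0.0880 and 0.0826), and GPC5 without any one Set (0.0846 to 0.8004). In horizontal cells CCDC82 was not called without Set 2 (0.0567), where transplanted sample 2, with 10 such cells, had already been left out.

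Rods and cones differed in the response of 60 genes among 16957, with 24 less reduced or more raised in rods and 36 the other way, and 1077 at an unadjusted p under 0.05. SCD (rod change minus cone change 2.05 ± 0.30, adjusted p = 1.99e-05), ACAT2 (1.58 ± 0.21, adjusted p = 6.52e-06) and MAP2 (1.10 ± 0.14, adjusted p = 1.93e-06) were less reduced in rods, and EYA2, a transcriptional coactivator, and NPSR1-AS1, an antisense transcript, had differences of 1.33 and 2.71. CCKBR, a cholecystokinin receptor, had a difference of -2.15 ± 0.27 (adjusted p = 1.61e-05) and SAMD7 one of -1.84 ± 0.30 (adjusted p = 0.000352). LTBP1 (-1.25), BMPR1B (-1.23) and ATP6V0D2 (-1.08) also differed in that direction. The count was 165 without replicate 1 and 19 without replicate 2, 18 with DESeq2, 106 with no expression filter, 9 with equal cells per sample and 159 with class by Set terms. For rods against Müller glia, edgeR called 0 genes, with 592 at an unadjusted p under 0.05, and DESeq2 called 0. That count was 15 without replicate 1, 39 without replicate 3, 29 with no expression filter, 2 with equal cells per sample and 177 with class by Set terms.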

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

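The tests of explanations and the counts of other splits of the samples in this part were chosen after the results were seen, whereas the interaction between rods and cones was tested as planned. The responses of rods and cones to transplantation differed for 60 genes by that interaction. The rod change minus the cone change was 2.71 for NPSR1-AS1, 2.05 for SCD, 1.58 for ACAT2, 1.33 for EYA2 and 1.10 for MAP2. It was -2.15 for CCKBR, -1.84 for SAMD7, -1.25 for LTBP1, -1.23 for BMPR1B and -1.08 for ATP6V0D2. Of the 10 splits of the 6 samples into groups of 3, 2 gave at least 60 genes, the real split included, and the highest other gave 91. That other split put both samples of Set 1 with transplanted sample 2, so it followed Set 1, and with class by Set terms the real count was 159. Without replicate 1, 2 or 3 the count was 165, 19 or 84. With 10 splits, no share under 0.05 can be reached.

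An unnamed cluster led by APOE, LCP1, TYROBP and CTSS, a profile of microglia or macrophages, held 240, 12 and 25 cells of transplanted samples 1, 2 and 3, and 0, 14 and 0 cells of cultured samples 1, 2 and 3. Its share of clone-named transcripts was 0.283 times that of cultured cells, and these cells entered no gene test.

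Cholesterol synthesis genes were lower in transplanted cones, with a median log2 change of -0.92 over 21 genes (quartiles -1.32 and -0.50). With cones matched by mitochondrial share within Sets, the median was -0.88 ± 0.211 and below 0 in each Set. This argued against cells with a high mitochondrial share as the whole cause. The median was -0.673 ± 0.280 with equal cells per sample and -1.214 ± 0.336 with sums thinned to equal UMIs, also below 0 in each Set. Random draws leave the expected proportions of genes unchanged, so these settings could not decide on numbers of cells or UMIs as a cause. Here ± is the SE over genes, which are not independent of one another. The 8 calls became 3 with equal cells, 0 with equal UMIs and 4 with matched cones, where fewer UMIs entered. The upper quartiles there (-0.16, -0.40 and -0.32) lay above 0.5 of the full median. A part of the fall therefore stays open for the mitochondrial share, and numbers of cells and UMIs stay open as causes. The rod change exceeded the cone change by a median of 0.60 (lower quartile 0.34). This argued against free RNA that shifts both classes of a sample by the same log2 amount. Its effect can differ with the level of a gene and the depth per cell, so free RNA in general stays open. The rod list was lower too (-0.37) and HMGCS1 fell in amacrine cells (-2.17), whereas edgeR with the block called 0 of 21 genes in Müller glia. Other differences between the eye and the dish stay open and were not tested.

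HLA-B, HLA-C, CEBPD and SOCS3 were higher in transplanted rods. RNA from the cells with microglia markers was argued against: the rise of 11 microglia markers in rods was at most 0.00452 of the rise that their ratio to each of the 4 genes in those cells would need, and their sum in rods was 1.78 ± 1.47 CPM in cultured and 2.41 ± 0.996 CPM in transplanted samples. A larger share of RNA from Müller glia, which Set 2 could not test, was argued against in Sets 1 and 3 for HLA-C and CEBPD (at most 0.0627 of the rise needed). It cannot be told apart for HLA-B and SOCS3, because the ratio passed the bound of 0.1 in 1 Set each (0.1134 and 0.1006). Only a rise of glial markers was read, so an unchanged share of glial RNA that carried more of these genes was not tested. T or NK cells were not tested, as no cluster carried their profile, and TRAC alone made up nearly all of the rise of their markers in rods. Handling of the grafts during recovery cannot be told apart from a response to the host, because immediate early genes were higher in transplanted rods by a median of 0.95 and no graft was handled in another way. A response to the eye or to injection may therefore explain the rise, as may handling, and an unchanged share of glial RNA stays open.

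GNGT2 was lower in transplanted Müller glia. Photoreceptor RNA in the droplets of these glia may account for it: in each of 5 samples the level of GNGT2 in Müller glia relative to photoreceptors was close to the median of the same ratio over photoreceptor transcripts, and the ratio furthest from 1 was 0.655. GNGT2 itself fell in rods (-2.05) and cones (-1.72), which would lower their free RNA. No biological explanation was tested for it.

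For the gene counts with the Set as a block, exchanging the labels within Sets gives 4 arrangements, too few for a share under 0.05, and 1 of 4, the real one, gave as many genes in rods (196, highest other 0), in cones (369, highest other 0) and in amacrine cells (18, highest other 2). Without the block, edgeR called 0 genes in the real split and in each of the other splits of rods, cones and amacrine cells, so 10 of 10 splits gave as many. The block counts at an unadjusted p under 0.05 were 2157, 2434 and 773, and DESeq2 without the block called 1, 5 and 0.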

How the results depend on the processing

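Settings that combine the block with another choice, leave out a Set or a rod cluster, or use class by Set terms were chosen after seeing the data; the others were planned. Of the results computed per setting for single genes, 2251 kept the direction and side of the threshold of the planned test, 1339 gained a call, 12 lost one and 8 reversed; for gene lists, 332 kept theirs, 216 lost a call and 8 reversed. With the Set as a block, every gene called in rods and cones kept its sign under DESeq2 and relative log expression factors (196 and 369 genes). The unblocked counts of 0 became 196 in rods, 369 in cones, 159 in Müller glia, 18 in amacrine cells and 19 in horizontal cells with the block, where the Set term takes out differences between Sets. DESeq2 without the block called 1, 5 and 2 in rods, cones and Müller glia. For rods, cones and Müller glia in that order, the block gave 114, 165 and 9 with DESeq2, 184, 323 and 153 with relative log expression factors, 287, 391 and 101 with no expression filter, 253, 189 and 154 with the stricter cell filter, and 238, 331 and 187 with doublets kept. It gave 72, 74 and 47 with equal cells per sample, where fewer cells and genes enter, 204, 379 and 177 with the host filter, 195, 135 and 406 at Leiden resolution 0.5 and 212, 248 and 51 at resolution 2. Rods gave 189 without cluster 11 and 32 without cluster 4. Each unblocked edgeR fit that left out a sample called 0 genes. Without Set 1, 2 and 3 the block gave 55, 188 and 448 in rods, 12, 448 and 557 in cones, and 0, 39 and 25 in amacrine cells. Without Set 2 it gave 150 in Müller glia and 14 in horizontal cells. In these classes Set 2 held no pair, so the same 2 pairs remained and no pair was tested by its loss. Leaving out Set 1 or 3 in Müller glia could not be fitted. The rod and cone interaction gave 106 with no expression filter, 18 with DESeq2, 9 with equal cells, 159 with class by Set terms, and 19 to 165 leaving out a replicate; rods against Müller glia gave 29, 0, 2, 177, and 0 to 39. The lists called without the block were 14, 14 and 16, and with it 12, 13 and 13. They went to 0, 0 and 0 with an estimated correlation, with fry, and with the block and an estimated correlation. Leaving out a sample gave 9 to 11 lists in rods and 9 to 14 in cones. Most reversals came from leaving out 1 sample. Nuclear oxidative phosphorylation turned higher in rods (adjusted p = 0.0217; range 5.33e-12 to 0.537 over the samples left out) and cones (0.0108; 8.31e-10 to 0.805) without cultured 1, and glycolysis in rods did too (0.624; 0.000115 to 0.624). The cone circadian list turned lower without transplanted 2 (0.943; 0.00177 to 0.943). In Müller glia, rod phototransduction (0.902; 7.50e-06 to 0.902) turned without transplanted 1, oxidative phosphorylation without cultured 3 (0.310) or transplanted 1 (0.132; 7.84e-10 to 0.311), and cell cycle without transplanted 3 (0.531; 2.61e-17 to 0.547). The cone share difference was -6.27, and -1.63 at Leiden resolution 0.5; that of rods was 7.79, with 4.93 at Leiden resolution 0.5, 13.8 with the stricter filter and 26.1 over named classes only. Without cultured 1 that of dividing progenitors was -0.858 (from -3.97), and without cultured 3 those of neurogenic precursors and bipolar cells were -0.681 and -1.13 (from -1.22 and -2.42). That of unnamed clusters was 16.8, and 7.53 with the stricter filter. The share difference of Müller glia ranged from -3.88 (without transplanted 1) to 4.67, and was -0.869 at Leiden resolution 0.5; that of astrocytes ranged from -1.82 to 0.0936, of mural cells from -1.44 to 0.102 (both highest without cultured 1), and of RPE from -0.463 to 0.140 (0.129 without cultured 2). Unblocked log2 changes ranged from -0.12 to 3.75 for TMEM176B in amacrine cells, -0.087 to 3.01 for S100A6 in rods and -0.13 to 3.60 for IFITM1 in Müller glia, each lowest without transplanted 1, and from -3.40 to 0.51 for CRABP1 in rods, highest without cultured 1. CRX in cones, never called, ranged from -0.26 to 0.19 (0.06 without transplanted 1), and was 0.00897 with the block and no filter and 0.14 with the block without Set 3. The cause of these changes was not tested except where stated. Cell number limits transplanted sample 2 most, with 149 rods and 45 cones.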

Other observations

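The counts and marker sums in this part were described after the data were seen, and no test was run on them. Retinal pigment epithelium markers were higher in the transplanted sample of 3 of 3 Sets within rods, at 347 ± 209 CPM in cultured and 597 ± 333 CPM in transplanted samples (sums of 10 markers, n = 3), and within cones, at 384 ± 112 and 741 ± 132 CPM. Endothelial markers in rods summed to 111.5 ± 46.2 and 147 ± 70.8 CPM, also higher in 3 of 3 Sets. Neurogenic precursor (1155 ± 728 and 1465 ± 934 CPM) and amacrine markers (511 ± 210 and 571 ± 253 CPM) in rods were higher in 3 of 3 Sets as well. Other sums were lower in 3 of 3 Sets, among them bipolar (735 ± 376 and 483 ± 240 CPM), horizontal (361 ± 29.6 and 266.5 ± 30.5 CPM) and retinal ganglion markers (55.0 ± 1.82 and 39.8 ± 7.64 CPM) in rods. Markers of T or NK cells in rods summed to 5.52 ± 5.10 and 21.1 ± 7.88 CPM, higher in 3 of 3 Sets.

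Cells below the 1st percentile of clone-named transcripts of cultured cells of the same Set made up 3.60%, 3.35% and 11.5% of transplanted samples 1, 2 and 3. The values of 1.004%, 1.01% and 1.03% in cultured samples follow from that cutoff. In Set 3 the median clone-named share over all kept cells was 5.26% in the cultured and 3.37% in the transplanted sample. It was 0.924% and 0.940% in Set 1, and 2.79% and 2.86% in Set 2. NQO1, an antioxidant enzyme, fell in rods (28.3 ± 11.2 to 7.20 ± 3.92 CPM) and cones (21.7 ± 7.30 to 6.89 ± 1.23 CPM, n = 3), with log2 changes of -1.75 and -1.41 (adjusted p = 0.0572 and 0.336 without Set 1). NFKBIA, an inhibitor of NF-kB, rose in rods by 1.16 and in cones by 1.45, and without Set 1 neither was called (adjusted p = 0.176 and 0.112). CDKN1A, a cell cycle inhibitor induced by p53, fell in cones from 37.3 ± 7.39 to 13.9 ± 5.81 CPM (-1.44), whereas BBC3, a p53 target that promotes cell death, rose from 29.8 ± 6.06 to 57.4 ± 6.11 CPM (0.94), calls that ended without Set 1 (adjusted p = 0.130 and 0.285) and, for BBC3, without Set 2 (0.102).

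Within a class, the cultured and transplanted samples of a Set, each taken as deviations from the mean of its group, resembled each other in Sets 1 and 3 and less so in Set 2, measured across genes that are not independent replicates. In rods the correlation between cultured and transplanted samples of the same Set was 0.92, 0.55 and 0.76 for Sets 1, 2 and 3. Cultured sample 2 correlated more with transplanted sample 3 (0.66) than with transplanted sample 2, and transplanted sample 2 more with cultured sample 3 (0.58). In cones and amacrine cells, too, cultured sample 2 correlated more with transplanted sample 3 (0.62 and 0.59) than with transplanted sample 2 (0.42 and 0.44).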
